A study of Arabidopsis thaliana with 2 samples.

How the data were processed

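The comparison had 2 libraries, 1 from control and 1 from MFZ-treated amiFPSa seedlings. Per the labels, total RNA was extracted from whole seedlings, and RNA from 3 independent pools of 100 mg fresh weight per treatment was mixed in equal amounts. Per the labels' protocols, 3 µg of RNA was fragmented and ligated to adaptors before cDNA synthesis, and the libraries were sequenced on an Illumina HiSeq2000 as paired reads of 100 nt. Whether the libraries kept strand is not given in the sources used here, so that reads of overlapping and antisense genes may be mixed. FastQC, TopHat2 2.0.7, Bowtie2 2.0.6, Cufflinks 2.0.2, Cuffdiff and the TAIR10 build are named in the submitters' processing notes.

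The deposited table has the layout of a Cuffdiff gene comparison, per the file headers. For each of 33557 genes it holds the FPKM in each library, the log2 fold change of MFZ-treated over control, a test statistic, a p-value, a q-value, a status and a call. The authors' p-values and q-values come from a test of 2 libraries without replicates. The deposited q-values equal a Benjamini-Hochberg adjustment of the deposited p-values over the 22455 genes with status OK, with a largest difference of 5.09e-07. The smallest deposited p-value is 5e-05 and the smallest q-value 0.0111.

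The deposited FPKM, log2 fold changes and statistics had passed through a spreadsheet that removed the decimal sign from numbers of at least 1 printed with 3 or more decimals. Numbers under 1 and numbers with up to 2 decimals are intact. The place of the sign was restored by trying each place in both FPKM values and keeping those whose log2 ratio matched the printed log2 fold change within a relative tolerance of 0.0002. This settled the log2 ratio of 23510 of the 23513 genes above 0 in both libraries. Another 2 genes had lost the exponent of a printed log2 fold change close to 0, and 1 had a whole number of FPKM. No gene kept more than 1 possible ratio. The level stayed open by a factor of 10 for 4580 genes and by up to 2 such factors for 13522, and was settled for 5411, but whether a gene reached 1 FPKM could be decided in each case. FPKM are printed here only where settled, or as the alternatives. In 20000 simulated gene pairs damaged the same way, 100% of log2 ratios were restored.

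The design set before the data were examined used log2(FPKM + 1). A pseudocount needs the level, so the ratios reported here are of FPKM without a pseudocount. This gives large folds for genes near 0 in the control. Where a pseudocount is quoted, it was added at the lowest level the digits allow. For a gene with an open level, any higher level would give a ratio closer to the one without a pseudocount. Genes above 0 in both libraries and of at least 1 FPKM in at least one were kept. Genes listed at 0 have no ratio. A gene was counted as higher or lower at an absolute log2 ratio of at least 1. With 1 library per group no test, standard error or replicate check was possible, and the authors' calls are quoted as theirs. The table gives no counts, so depth is unknown and no interval was computed.

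There were 34 gene lists with 435 entries, fixed before the data were examined. Members were matched by locus, and 1 entry (TPS11) was left out because the reference gives that symbol to another locus. Locus identifiers were matched to NCBI gene records of the TAIR10.1 assembly for 32810 genes, for names only, because the gene names in the table had been shortened and 17 had become dates. For 16 listed genes the symbol rests on the lists alone. Of the list entries, 58 share their deposited coordinates with an overlapping gene, and their values are less certain. Printed starts count from 1. Each list's median was placed among 10000 random lists of the same size, drawn from genes in the same of 20 equal bins of mean log2 FPKM, with an open level set to the middle of its alternatives. A list stood apart below percentile 2.5 or above 97.5, and lists with fewer than 5 measured members got none. In simulated lists drawn from the 19916 genes of the MFZ-treated against control comparison, 8 of 240 unshifted lists stood apart. With members raised by 1 log2 unit, 51 of 60 lists of 5 genes and 60 of 60 lists of 20 genes were found, and with 0.5 log2 units 25 and 59.

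Genes were named by a rule fixed before the data were examined. It took FPS1 and FPS2, the 10 highest and 10 lowest ratios among genes with a symbol, status OK and at least 5 FPKM in a library, and from each list up to 5 measured members with the largest absolute log2 ratio, plus members that moved against the rest. The 5 FPKM limit used the lowest level the digits allow, so that a gene with an open level could be left out although it lay above the limit. Other names were chosen after their values were seen, which in the report are members called in the authors' deposited table, FIT and IRT1, the ends of a range, and genes listed at 0. Alternatives were a pseudocount of 0.1 or 1, centring on the median gene, other FPKM filters, status OK only, 1.5-fold and 4-fold rules, a q-value of 0.01, list means, 10 bins, matching on the implied standard error, and members at 0 placed on top. The implied standard error is the absolute log2 ratio over the deposited statistic. The statistics had lost decimal signs too, so their decimal place may be misread for some genes. Implied values were 9.39 for NATA1, 9.18 for AIG1 and 8.61 for PR1, against 0.869 for JRG21 and 0.904 for SARD1. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.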

Results

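Transcript levels were measured by RNA sequencing in whole 8-day-old seedlings of an Arabidopsis thaliana line in the Col-0 background. The line carries an artificial microRNA, amiFPSa, directed against farnesyl diphosphate synthase (FPS), and the chemical MFZ induces the silencing. Farnesyl diphosphate synthase makes farnesyl diphosphate, a precursor of sterols and other isoprenoids. Seedlings grew for 3 days on MS medium and for 5 more days on MS medium without MFZ (control) or with 30 µM MFZ. RNA from 3 pools of seedlings per treatment was mixed in equal amounts, so that each group was represented by 1 library and the values carry no replicate error. The comparison of the 2 libraries addresses how seedlings with silenced FPS differ from uninduced seedlings of the same line, with the series title naming chloroplast development, jasmonate-related responses and iron deficiency responses. MFZ was absent from the control medium, and seedlings given MFZ without the transgene were not analysed here, so that the chemical and the silencing changed together. Levels are FPKM, that is fragments scaled by transcript length and by the fragments mapped in the library. The sequencing depth is unknown, since the table gives no read counts.

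Both target genes were lower in the MFZ-treated library. FPS1 (AT5G47770, chromosome 5, 19345173 to 19347629, TAIR10) was 5.59-fold lower, a log2 ratio of -2.48. FPS2 (AT4G17190, chromosome 4, 9648527 to 9650912) was 4.39-fold lower, a log2 ratio of -2.14. The authors' deposited table called FPS1, with a q-value of 0.0111, and did not call FPS2, with a q-value of 0.101. Those q-values compare the 2 libraries and not the conditions. Control levels were 6.01 or 60.1 FPKM for FPS1 and 26.1 or 261 FPKM for FPS2, because the deposited digits leave the decimal place open while fixing the ratio. With the planned pseudocount of 1, at the lowest levels the digits allow, FPS1 was 3.38-fold lower.

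Among 19916 genes that reached 1 FPKM in a library and lay above 0 in both, 1406 were at least 2-fold higher and 895 at least 2-fold lower with MFZ. The larger ratios lay on the higher side, with 174 genes at least 16-fold higher and 8 at least 16-fold lower. At a 1.5-fold rule the lower side held more genes, with 2736 lower and 2477 higher. The median log2 ratio of all these genes was -0.05. Another 35 genes that reached 1 FPKM with MFZ were listed at 0 in the control, and 30 that reached 1 FPKM in the control were listed at 0 with MFZ. The authors' test was not completed for 3 of those 35 and 16 of those 30 genes, so that a listed 0 may be a missing estimate. The authors' deposited table called 168 of 22455 genes tested. Of these, 116 were higher and 16 lower with a value above 0 in both libraries, 35 were listed at 0 in the control and 1 was listed at 0 with MFZ. The number past the 2-fold rule was 3627 without the FPKM filter. With a pseudocount of 1 at the lowest level the digits allow it was 1447, with 985 higher and 462 lower. Genes with open levels may lie above that level, so the drop does not show how many genes lay near 0. Higher or lower values refer to the side of a ratio, and 2-fold counts to the genes past the size rule.

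The highest ratios among genes that reach 5 FPKM at the lowest level the digits allow belonged mainly to genes almost silent in the control. NATA1 went from 0.151 FPKM in the control to 266 FPKM with MFZ, a 1755-fold difference. The tyrosine aminotransferase gene TAT3 was 1191-fold higher and the pathogenesis-related gene PR1 719-fold higher, at 66.3 and 164 FPKM with MFZ. CSLA01, PUB54, scpl30, the glutathione transferase gene GSTU3, AIG1, the alternative oxidase gene AOX1D and ELI3-2 were between 379-fold and 1330-fold higher. None of these 10 genes was called in the authors' deposited table, where PR1 had a q-value of 0.475 and NATA1 of 0.543. At the other end, the iron-sulfur protein gene NEET was 16.3-fold lower, the nicotianamine synthase gene NAS3 12.9-fold lower and PORA 9.66-fold lower. The cold-regulated genes COR413IM1 and COR15B were 8.68-fold and 7.77-fold lower, the fructose-bisphosphate aldolase gene FBA5 8.66-fold lower and TCL1 6.38-fold lower. The remaining names among the 10 lowest were the small nucleolar RNAs SNOR108 and SNOR111 and the plastid ribosomal protein gene RPL32, at log2 ratios of -3.29, -2.84 and -3.06. The authors' deposited table called NEET, COR413IM1, FBA5 and COR15B among these 10.

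Most listed genes acting before and after FPS in isoprenoid synthesis stayed within 2-fold between the libraries, while 5 sterol genes were higher. All 11 measured genes of the mevalonate pathway, which supplies FPS with its substrates, stayed within 2-fold, between MVK at a log2 ratio of -0.59 and PMK at 0.40. The other members farthest from 0 were AACT1 at -0.49, HMG2 at -0.31 and IPP2 at 0.27. Of 27 genes of squalene and sterol synthesis, 22 stayed within 2-fold and 5 were higher. Those 5 were the lanosterol synthase gene LAS1, 24.5-fold higher from 0.201 FPKM, SQE6 at a log2 ratio of 2.08, the sterol C-22 desaturase genes CYP710A1 at 1.82 and CYP710A2 at 1.26, and SQE4 (AT5G24140) at 1.21. With a pseudocount of 1 at the lowest levels the digits allow, CYP710A2 and SQE4 fell short of 2-fold and 3 genes passed it. The median of the mevalonate list stood at percentile 57.9 and that of the sterol list at percentile 51.3 of random lists matched on expression. All 6 measured brassinosteroid synthesis genes were within 2-fold, with CPD the farthest at a log2 ratio of -0.95 and CYP90D1, ROT3, DWF4 and DET2 at 0.35, 0.27, 0.19 and -0.12 (percentile 82.7). In a list of genes for other uses of prenyl diphosphates, of which PPT1 and TPS04 do not take farnesyl diphosphate itself, PPT1, PLP, ERA1 and LEW1 were within 2-fold, at log2 ratios of -0.59, 0.29, -0.18 and 0.13, too few for a percentile. The geranyllinalool synthase gene TPS04 was listed at 0 in the control and was called in the authors' deposited table.

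Most listed genes for photosynthesis were at least 2-fold lower in the MFZ-treated library, in both the nuclear and the plastid genome. All 19 measured light-harvesting antenna genes had lower values and 18 were at least 2-fold lower, with a median 2.78-fold lower that lay below all random lists (percentile 0). LHB1B1 went from 4846 to 926 FPKM, and LHCB2.3, LHCB4.2, CAB3 and CAB2 had log2 ratios of -1.96, -1.67, -1.64 and -1.55. LHCB4.3 differed least, at -0.34. All 26 genes of the photosystem core and Rubisco had lower values, 20 of them at least 2-fold lower, with a median 2.33-fold lower (percentile 0). Its members farthest from 0 were PSAN, PSAF, PSAO, RBCS3B and PSBW, at log2 ratios of -1.91, -1.79, -1.67, -1.55 and -1.54. Of 10 listed plastid-encoded genes, 9 were at least 2-fold lower, among them PSAA at -1.95, RBCL at -1.82, PSBC at -1.81, PSBA at -1.79 and PSAB at -1.54, while ATPA was at -0.30 (list median -1.39, percentile 0). PSBA was at 5.87 or 58.7 FPKM in the control, against 15272 FPKM for the nuclear gene RBCS1A. How fully plastid transcripts were captured in each library was not tested. None of the measured genes of these 3 lists was called in the authors' deposited table. The statistics of the authors' deposited table imply a median standard error of 1.23 log2 units for the antenna genes, against 0.56 over tested genes of at least 1 FPKM, and none of the 87 genes at or above 1000 FPKM in the control was called. Of those 87 genes, which include most antenna and photosystem genes, 55 passed the 2-fold rule. The random lists also drew on less abundant genes, so percentile 0 is not a comparison with equally abundant genes alone. Closely related copies, such as the CAB and RBCS genes, share reads, and CAB1 was listed at 0 in the control without a completed test and was left out. Root markers, by contrast, had a median log2 ratio of 0.28.

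Pigment and plastid genes mostly had lower values that stayed within 2-fold. All 16 chlorophyll synthesis genes had lower values and 7 were at least 2-fold lower, with a median 1.92-fold lower (percentile 0). The protochlorophyllide reductase genes PORA and PORB were at log2 ratios of -3.27 and -1.84, HEMA1 at -1.86, CHLM at -1.28 and GUN5 at -1.22. With a pseudocount of 1 at the lowest levels the digits allow, 4 genes were at least 2-fold lower, with CHLM and GUN5 among those that fell short. Of 14 carotenoid synthesis genes, LUT2 at -1.02 was at least 2-fold lower and 13 were within 2-fold, including LUT1 at -0.78, PDS3 at -0.74, CRTISO at -0.72 and Z-ISO at -0.71, with BCH2 at 0.21 and BCH1 at 0.05 on the other side (median -0.60, percentile 0.010). LUT2 was within 2-fold with either pseudocount at the lowest level the digits allow, and after centring on the median gene. All 7 genes of the plastid MEP pathway had lower values within 2-fold, between ISPF at -0.37 and CLA1 at -0.98, with DXR and ISPD at -0.80, HDS at -0.62 and HDR at -0.47 (median -0.62, percentile 1.29). With a pseudocount of 1 at the lowest levels the digits allow, the MEP list lay at percentile 2.62, outside the range called apart. The 19 genes of the plastid transcription machinery all had lower values, 1 at least 2-fold lower and 18 within 2-fold, with GLK2 at -1.09, PTAC3 and PTAC14 at -0.92, SIG1 at -0.89 and SIG4 at -0.85 (median -0.58, percentile 0.010). Among 5 chlorophyll breakdown genes the values went both ways, from NYC1 at -1.32 through NYE1 at 0.01, PPH at 0.18 and PAO at 0.40 to CLH1 at 2.80 (percentile 90.8). The authors' deposited table called CLH1, at a q-value of 0.0111.

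Jasmonate genes were among the groups with the highest ratios. All 25 measured jasmonate response genes had higher values and 23 were at least 2-fold higher, with a median 12.4-fold higher that lay above all random lists (percentile 100). With a pseudocount of 1 at the lowest levels the digits allow, that median was 3.72-fold higher. Beside TAT3, the defensin genes PDF1.2c and PDF1.2 had log2 ratios of 7.27 and 6.46, PDF1.2b had 4.75, and the vegetative storage protein gene VSP1 went from 30.7 to 1317 FPKM. The authors' deposited table called 9 members of this list as higher, which were VSP1, CYP94B3, CORI3, the repressor genes JAZ1, JAZ5, JAZ6, JAZ9 and JAZ10, and THI2.1, listed at 0 in the control. Of 18 measured jasmonate synthesis genes, 11 were at least 2-fold higher and 7 within 2-fold (list median at percentile 100). The lipoxygenase gene LOX4 and the allene oxide cyclase genes AOC1 and AOC3, at log2 ratios of 3.35, 2.88 and 2.81, were called in the authors' deposited table. LOX2 was 5.67-fold higher and AOC2 was at 2.24, whereas FAD7, FAD8, JAR1 and FAD3, 3 of them fatty acid desaturase genes, lay between -0.33 and -0.13. Copies of the PDF1.2, VSP and AOC genes share reads, which leaves the split within each family uncertain.

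Among iron genes, 17 of 34 for deficiency responses were at least 2-fold higher and 8 of 12 for storage at least 2-fold lower. All measured genes of 2 groups of regulators, the Ib bHLH transcription factors and the IMA peptides, were at least 2-fold higher. IMA2 (AT1G47395) was 24.4-fold higher and BHLH38 16.5-fold higher, and IMA1 (AT1G47400), BHLH100 and BHLH39 had log2 ratios of 3.84, 3.82 and 3.49. These 5 genes and IMA3 (AT2G30766) were the 6 members called in the authors' deposited table. In the list of iron uptake and the iron deficiency response 17 genes were within 2-fold, and the median was 1.93-fold higher (percentile 100). It was 2.92-fold higher among genes that reach 5 FPKM at the lowest level the digits allow. The iron transporter gene IRT1, at a log2 ratio of 0.82, and the transcription factor gene FIT (AT2G28160), at -0.79, were within 2-fold. In the list of iron storage and sufficiency 4 genes were within 2-fold, and the median was 4.70-fold lower (percentile 0). It was 2.97-fold lower with a pseudocount of 1 at the lowest levels the digits allow. NEET, FER1, FER4 and VTL5, of which FER1 and FER4 encode ferritins, were called in the authors' deposited table. FER1 was 6.02-fold lower, NAS3 was at a log2 ratio of -3.69, VTL2 at -2.51 and VTL5 at -2.44, whereas YSL3 was at 0.90. FER1 and IMA3 each share their deposited coordinates with an overlapping gene, so their values and calls are less certain.

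**Figure D1:**
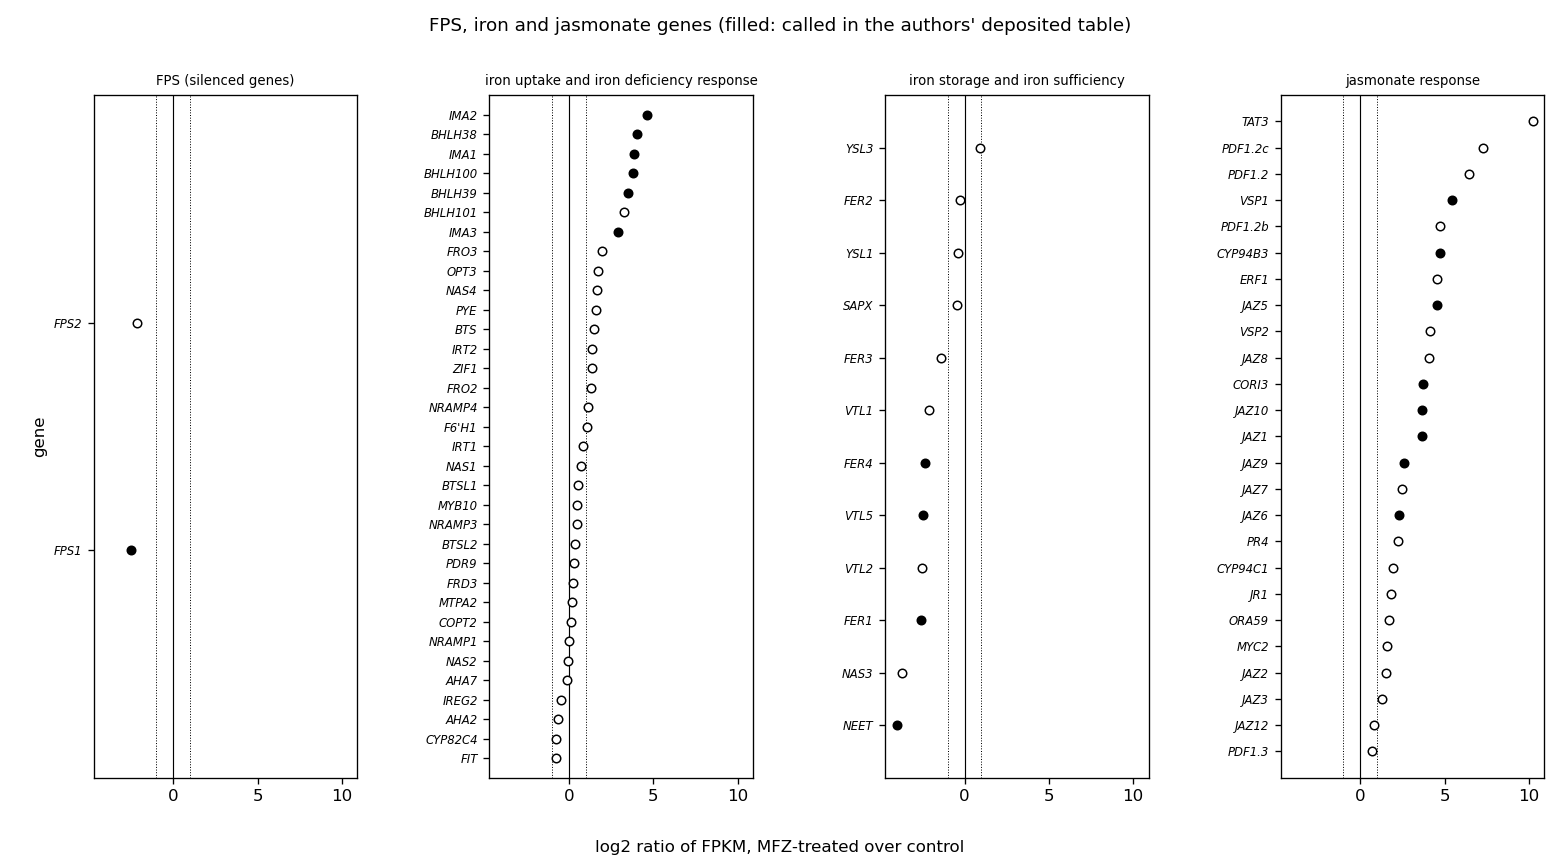
Log2 ratio of FPKM, MFZ-treated over control (horizontal axis), of each measured gene (vertical axis) in 4 lists, with 1 library per group. Filled points were called in the authors' deposited table and dotted lines mark a 2-fold difference. FPS1 and FPS2 lie at -2.48 and -2.14, and in the iron deficiency list IMA2 at 4.61 and FIT at -0.79 are the ends of the range.

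Among other nutrient lists, the phosphate starvation list stood above and the copper deficiency list below the range of random lists, and the zinc deficiency list stood within it. The copper deficiency list had a median log2 ratio of -0.49 (below the percentile limit of 2.5), with FSD1 at -1.36, FRO4 at -1.26, ZIP2 at -0.51, CCH at -0.49 and YSL2 at 0.70. Using the mean put it at percentile 3.30, and matching on the implied standard error at 2.95, both outside the range called apart. FRO4 was within 2-fold with a pseudocount of 1 at the lowest level the digits allow. All 6 measured zinc deficiency genes were within 2-fold, IRT3, ZIP1, ZIP4, ZIP5 and HMA2 being at 0.64, 0.59, 0.49, 0.27 and 0.15 (median 0.38, percentile 96.8). All 9 phosphate starvation genes had higher values and 5 were at least 2-fold higher, with SPX3 at 2.92, PS2 at 2.60, MGD3 at 1.87, IPS1 at 1.33 and SPX1 at 1.31 (median 2.48-fold higher, percentile 99.96).

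Defence and stress lists differed in direction. All 11 salicylate response genes had higher values and 8 were at least 2-fold higher, with PR1, PR2, WRKY70, NIMIN1 and EDS5 at log2 ratios of 9.49, 7.40, 4.12, 3.56 and 1.92 (median 3.18-fold higher, percentile 100). The salicylate median was 6.68-fold higher among genes that reach 5 FPKM at the lowest level the digits allow, and the mean of the list 7.90-fold. WRKY70 was the member called in the authors' deposited table. All 9 measured heat shock genes had higher values, 7 at least 2-fold higher, with HSP22.0, HSP17.6II, HSP17.6A, HSP23.6-MITO and HSP17.4 at 6.75, 5.76, 5.11, 3.49 and 3.00 (median 7.99-fold higher, percentile 99.96). At the lowest levels the digits allow, the heat shock median was 2.82-fold higher with a pseudocount of 1 and 5.09-fold among genes of at least 5 FPKM. HSP23.6-MITO was within 2-fold with that pseudocount. HSP22.0 reached 1.87 FPKM from 0.0174 FPKM. HSP21, listed at 0 in the control and at 0.943 FPKM with MFZ, was called in the authors' deposited table. In the unfolded protein response list 1 gene was at least 2-fold higher and 8 had higher values within 2-fold, BIP3 being at 2.64 and BIP2, BZIP60, ERDJ3A and BIP1 at 0.80, 0.79, 0.79 and 0.76 (median 0.76, percentile 99.9). Of 17 measured abscisic acid and cold response genes, 8 were at least 2-fold lower and 9 within 2-fold, with a median of -0.68 (percentile 0). With a pseudocount of 1 at the lowest levels the digits allow, 6 of these genes were at least 2-fold lower. The median was -1.74 among genes that reach 5 FPKM at the lowest level the digits allow. COR15B at -2.96 and RD29A at -2.35 were called in the authors' deposited table, CBF3, COR15A and RAB18 were at -2.45, -1.74 and -1.52, and DREB2A was at 0.46. Of 8 measured peroxide and superoxide scavenging genes, FSD1 at -1.36 passed the 2-fold rule, with APX1, CAT3, CAT1 and CAT2 at -0.79, -0.77, -0.64 and -0.61 and CSD1 at 0.54 (median -0.63, percentile 0.27). Using the mean put this list at percentile 3.23, outside the range called apart.

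All 12 measured anthocyanin synthesis genes had higher values, 11 of them at least 2-fold higher (median 5.50-fold higher, percentile 100). The dihydroflavonol reductase gene DFR went from 8.04 to 110 FPKM, and the regulator gene PAP1 was 12.3-fold higher. UF3GT, LDOX and GSTF12 were at log2 ratios of 3.30, 3.27 and 2.72, and these 5 genes were called in the authors' deposited table. All 8 indole glucosinolate genes had higher values and 5 were at least 2-fold higher, with MYB51, CYP79B2, CYP83B1, CYP79B3 and SOT16 at 1.93, 1.86, 1.72, 1.63 and 1.22 (median 2.68-fold higher, percentile 100). Of 9 aliphatic glucosinolate genes, MAM3, CYP79F2 and FMOGS-OX1 were higher at 1.53, 1.17 and 1.13, and 6 were within 2-fold, with CYP79F1 at 0.38 and MYB28 at -0.27 (median 0.14, percentile 89.0). With a pseudocount of 1 at the lowest levels the digits allow, MAM3 alone of these 9 was at least 2-fold higher.

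Markers of tissues and of growth were mostly within 2-fold. Root markers had a median log2 ratio of 0.28 (percentile 99.1), with 14 of 16 within 2-fold, PRP1 at 1.92, PLT2 at 1.11, PRP3 at 0.72, CASP4 at 0.49, and NRT2.1 at -0.53. The root list lay at percentile 89.5 by the mean and 85.4 among genes that reach 5 FPKM at the lowest level the digits allow. Both are within the range not called apart, and PLT2 was within 2-fold with a pseudocount of 1. The 5 measured shoot meristem and leaf polarity markers were within 2-fold, AS1, KAN1, YAB3, STM and FIL being at -0.76, 0.40, -0.32, 0.25 and 0.02 (percentile 65.5). All 7 stomatal lineage markers had lower values, with SDD1 at -1.93, EPF1 at -1.70, TMM at -1.16, MUTE at -0.51 and SPCH at -0.50 (median -0.51, percentile 2.87). All 9 mitotic genes had lower values within 2-fold, with KN at -0.79, CDKB1;2 at -0.60, CDKB2;1 at -0.55, CYCB1;2 at -0.42 and CYCB1;4 at -0.42 (median -0.42, percentile 2.53). Both lists lay close to the percentile limit of 2.5 and their side of it depended on the setting, the mitotic list ranging from 0.98 to 10.9 and the stomatal list from 0.020 to 3.21. The 3 measured seed storage genes were SESA2 at 5.87, from 0.0477 FPKM, CRA1 at 0.09 and OLEO2 at -0.12. The 10 reference transcripts were within 2-fold, from UBC21 at -0.42 to UBQ10 at 0.17 (median -0.19, percentile 19.1).

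**Figure D2:**
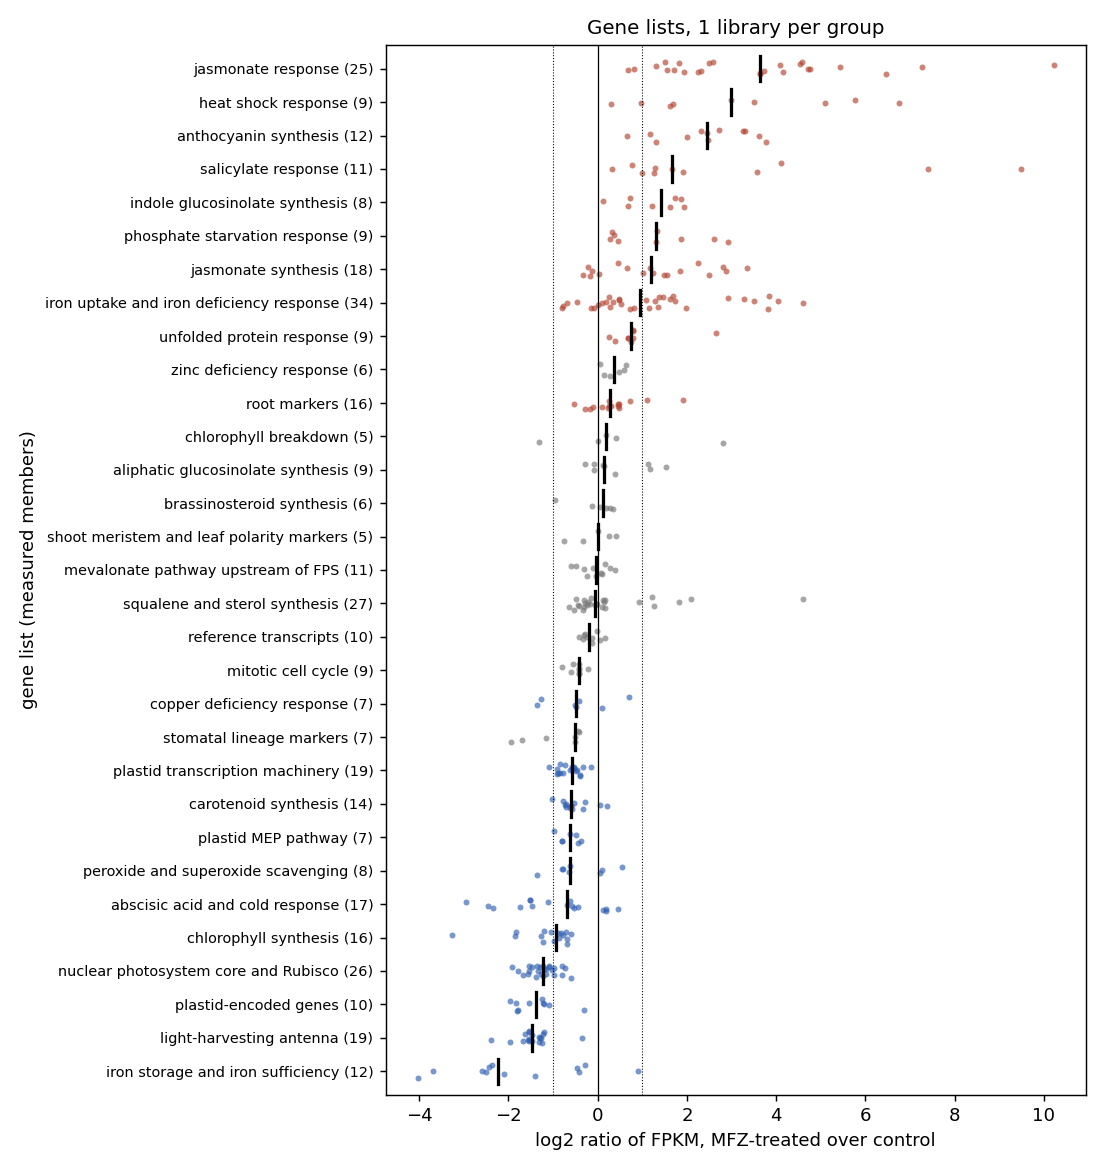
Log2 ratio of FPKM, MFZ-treated over control (horizontal axis), of the measured members of each of 31 gene lists (vertical axis, number of measured members in brackets), with 1 library per group. Points are genes, bars are list medians, dotted lines mark a 2-fold difference, and colour marks lists above (red), below (blue) or within (grey) the range of random lists. As plotted, without a pseudocount, medians run from -2.23 for iron storage to 3.63 for the jasmonate response. With a pseudocount of 1 at the lowest levels the digits allow, they run from -1.57 for iron storage to 2.06 for anthocyanin synthesis, with the jasmonate response at 1.90.

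Of the 31 lists with at least 5 measured members, 10 lay above and 11 below the range of random lists. About 1.55 would lie outside it if the genes of a list varied independently, which was not shown for these lists. Several lists also cover topics that the series title names, so these counts are not a comparison with chance. The percentiles describe these 2 libraries, and genes of one list are not independent replicates.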

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

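The pseudocount of 1 was the planned choice, and the ratio without a pseudocount used as the main value was chosen after seeing the data. Evaluating pseudocounts at the lowest level the digits allow, the filter of 1 FPKM in both libraries, the matching on the implied standard error and the placing of genes at 0 were also chosen then. FPS1 and FPS2 stayed at least 2-fold lower under both pseudocounts and centring, FPS1 by 3.38-fold with a pseudocount of 1 against 5.59-fold. That pseudocount also moved the medians of the jasmonate response, heat shock and iron storage lists to 3.72-fold, 2.82-fold and 2.97-fold. With it, genes at least 2-fold higher numbered 22 for jasmonate response, 9 for jasmonate synthesis and 14 for iron deficiency. They numbered 7 for the salicylate list and 5 for the heat shock list. Genes at least 2-fold lower numbered 7 for the plastid-encoded list and 6 for the abscisic acid and cold list. Of 443 single genes, 23 lost the 2-fold difference with a pseudocount of 1, 1 with 0.1 and 2 by centring, which 2 others gained. The main counts were 2301 genes past the 2-fold rule, 1406 higher and 895 lower. The count was 3627 without a filter (2144 higher, 1483 lower), 1326 at 5 FPKM (797 and 529), 5213 at 1.5-fold (2477 and 2736), 693 at 4-fold (599 and 94), and 1447 with a pseudocount of 1 (462 lower). At 1 FPKM in both libraries 912 were higher. The filters and fold rules change which genes are counted by construction. The 5 FPKM filter and both pseudocounts used the lowest level the digits allow, so open levels may add to the changes seen with them. No gene was called at a q of 0.01, where the authors' count of 168 became 0, since the smallest q-value is 0.0111. Of 300 alternative list medians, 282 kept their side of the percentile limits and none reversed. The cause of the others was not tested. Lists that no longer stood apart were the MEP pathway with a pseudocount of 1 (median -0.41), copper deficiency by the mean (-0.46) and matched on the implied standard error (-0.49), scavenging by the mean (-0.44), and root markers at 5 FPKM (0.28) and by the mean (0.35). The stomatal list passed the limit with a pseudocount of 1 (-0.45), at 5 FPKM (-0.83), by the mean (-0.95), and, at an unchanged median of -0.51, matched on the implied standard error and with genes at 0 on top. The mitotic list passed it with pseudocounts of 0.1 (-0.42) and 1 (-0.38), by the mean (-0.47), and, at -0.42, with status OK only, 10 bins, matching on the implied standard error and genes at 0 on top. Rescaling to TPM was not run, because the sum of FPKM is unknown while levels are open. No paired analysis was possible because each group has 1 library. Without counts, what depth limits could not be worked out.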

Other observations

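All gene groups and tests in this part were chosen after the values were seen. Among defence genes outside the lists, the camalexin synthesis genes CYP71A12, CYP71A13 and PAD3 were 23.5-fold, 21.0-fold and 5.06-fold higher in the MFZ-treated library, and all 3 were called in the authors' deposited table. The salicylate-linked genes PBS3, CBP60G and DMR6 were higher at log2 ratios of 4.56, 3.67 and 2.13. These 3 were called in the authors' deposited table, whereas SARD1, 191-fold higher from 0.135 FPKM, was not. JRG21, 343-fold higher from 0.190 FPKM, was not called either. ARGAH2, ST2A and the sugar-starvation genes DIN11 and ASN1 were 9.86-fold, 7.35-fold, 47.6-fold and 4.39-fold higher and called in the authors' deposited table. In volatile terpene synthesis, CYP82G1 was 303-fold higher from 0.00883 FPKM, beside TPS04 listed at 0 in the control, while TPS03 was 9.31-fold lower. Of 54 WRKY transcription factor genes 21 were at least 2-fold higher and 1 lower (median 0.63, percentile 100), and of 46 glutathione S-transferase genes 15 were higher and none lower (median 0.45, percentile 100). A group of 18 genes gathered as plasma membrane aquaporins and the 15 tubulin genes all stayed within 2-fold, with medians of -0.39 and -0.40 (percentiles 0.45 and 0.74). The 18 genes may include genes other than plasma membrane aquaporins, so their median need not describe that family. The other families examined were NAC factors, UDP-glycosyltransferases, cysteine-rich receptor-like kinases, AUX/IAA repressors, BBX factors and histone H2A genes, with medians of 0.41, 0.46, 0.35, -0.33, -0.51 and -0.46.

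All 59 measured plastid genome genes had a median log2 ratio of -0.51, with 20 at least 2-fold lower, 1 higher and 38 within 2-fold (percentile 0). Among them, the 28 genes for photosystems, cytochrome complex, ATP synthase and Rubisco had a median of -1.22 with 17 at least 2-fold lower (percentile 0). The 19 ribosomal protein and RNA polymerase genes had a median of -0.22 with 3 at least 2-fold lower (percentile 8.34), and the 6 NDH complex genes -0.02 with none past the rule (percentile 44.5). Single members overlapped between groups, such as RPL32 at -3.06 and ATPA at -0.30. The 13 measured mitochondrial genome genes had a median of 0.06 (percentile 56.8). The difference between the plastid groups was not tested, and neither was the capture of plastid transcripts.

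The antenna list had lower values throughout. One scaling factor set by a few abundant transcripts would have lowered the reference transcripts as far as the antenna genes, but their median was -0.19 (SD 0.19 among 10 genes) against -1.47, which argues against scaling as the cause. A smaller share of green tissue as the whole cause would lower all abundant members by about one amount. The 10th to 90th percentile range of the 42 antenna, photosystem core and Rubisco genes of at least 1000 FPKM in the control was 0.70 log2 units, against 0.39 in the reference transcripts. The limits set were a range no wider than in the reference transcripts if this were the whole cause, and over 2 times as wide if not. The observed range was wider but less than 2 times as wide, so it met neither limit. A smaller green share and lower transcript levels per cell therefore cannot be told apart without replicate error. An effect of MFZ apart from the silencing also stays open, untested.

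Within the iron deficiency list, the 14 measured genes of the Ib bHLH, IMA and PYE network were at least 2-fold higher (median 2.45). They include transporter and enzyme genes such as OPT3, FRO3 and NAS4. The 17 measured genes placed with the root regulator FIT, itself at -0.79, had a median of 0.27, with 3 at least 2-fold higher and none lower. With a pseudocount of 1 at the lowest levels the digits allow, NRAMP4 in the network and IRT2 and F6'H1 in the FIT group fell short of 2-fold. AHA2, FRD3 and NRAMP3, at -0.68, 0.26 and 0.47, were placed in neither group. The genes were placed with their values in view, so the gap of 2.18 is a description and not evidence of a split. Root markers, which a smaller share of root tissue would lower, had a median of 0.28 (SD 0.58, 16 genes) and were not lower as a group. The gap was made by the placing and sets no amount for them to fall by, so a small loss of root tissue stays open. No biological explanation was tested.

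Calls in the authors' deposited table may depend on an exact 0 in the control more than on the size of the increase. Of 113 tested genes listed at 0 in the control and under 1 FPKM with MFZ, 18 (15.9%) were called, and of 32 listed at 0 in the control and at least 1 FPKM with MFZ, 17 were. Of 90 tested genes above 0 but under 1 FPKM in the control, at least 1 FPKM with MFZ and at least 32-fold higher, 4 (4.44%) were called. The median level with MFZ, taken at the lowest the digits allow, was 0.301 FPKM in the first group and 8.12 FPKM in the second. This is what a call set by the 0 itself predicts, as a hypothesis, and no biological explanation was tested.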
